A study of Arabidopsis thaliana with 4 samples.

How the data were processed

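RNA from expanded leaves of Arabidopsis thaliana grown in short days was measured on 4 single-colour oligonucleotide arrays, 2 from the Columbia accession and 2 from the jaw-D mutant, per the labels. The series concerns overexpression of the microRNA miR319a. Each array's genotype was taken from its sample description, and its replicate number from the letter in its title. The labels do not say whether replicates came from separate plants, pools or extractions, so the p-values measure only the spread between these samples, which may be technical. No date or other batch is given, and 0 columns of the value table were left unassigned.

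The deposited values are probe-set signal intensities on a linear scale, read as such from the values themselves, since each array holds positive numbers and a few zeros with 1 decimal, and the largest signals ran from 11151 to 15234. The mean of each array after leaving out the lowest and the highest 2% of all rows was 200.0, so the arrays had already been scaled to a common level by the authors. The software, the summary method and the scaling target are not given in the sources used here. The deposited table carries no detection calls, so the background level of a single probe set is unknown and dim signals have no bound of their own.

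The table held 22810 rows, of which 64 were array controls and were left out of the tests, leaving 22746 probe sets. Of these, 13513 were paired with 1 gene by the platform annotation used here, 503 with several genes, and 8730 were not named in it. Through their gene identifiers, 13436 of the probe sets with 1 gene were matched to 13286 loci of the TAIR10.1 reference, which was used only for names and for the order of genes. Probe sets with several genes entered the tests and are not named. Of several probe sets for a gene, the one with the highest mean over the 4 arrays was used for the lists and the genes of the naming rule. The remaining called genes are given by the probe set that was called.

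Signals were transformed as log2(signal + 16), so a fold change is on the log2(signal + 16) scale and understates the change of dim probe sets. Median log2 values lay between 6.50 and 6.54 over the 4 arrays, inside the allowed range of 0.1, and no further normalization was applied. Differences, jaw-D minus Columbia, were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 2 residual and 3.76 prior degrees of freedom. All tests were two-sided, with Benjamini-Hochberg adjustment over the 22746 probe sets and a threshold of 0.05. An exact permutation test of 2 arrays against 2 cannot go below p = 0.333, so none is given for single genes. The number of arrays limits the precision of every value. Figures were drawn with matplotlib 3.10.9.

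Before the data were examined, 26 gene lists with 299 members were fixed. They covered the TCP targets of miR319, MYB genes listed as targets of miR319 or miR159, other TCP genes and the genes beside MIR319A. Further lists were jasmonate biosynthesis and response, auxin, cytokinin, gibberellin, leaf polarity, organ boundaries, growth-regulating factors, cell cycle, senescence and photosynthesis. The rest were salicylate defence, anthocyanin synthesis, flowering time, the clock, touch and temperature responses, reference genes, and markers of flower, root, trichome, stomatal and vascular cells. The annotation used here named only 42 of the members, in 18 of the lists, and 14 lists had the 2 or more members that a list test needed. None of the 5 TCP targets of miR319 was named, nor was any of the 6 MYB genes listed as targets of miR319 or miR159. MIR319A was not named either, so these are not analysed here. The lists for salicylate defence, growth-regulating factors, flowering time, organ boundaries, flower and vascular cells also had 0 named members. Lists were tested with camera at its preset correlation of 0.01, adjusted over the 14 lists, with an estimated correlation and fry as alternatives.

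The genes named in the text follow a rule fixed before the data were examined. It takes every measured gene of the TCP and MYB target lists and of the genes beside MIR319A. It then takes the 8 largest rises and falls among called probe sets of 1 gene with replicates apart and a mean signal at or above the median of all probe sets. A direction with fewer such genes is filled to 4 by the smallest unadjusted p, with values only. Last come up to 3 members of each other list with the smallest unadjusted p. The remaining called genes, and those in the closing observations, were chosen after their values were seen.

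The alternatives fixed before the data were examined were quantile normalization, median centring, filters on dim probe sets, a floor, pseudocounts of 1 and 64, trended and robust variance moderation, the replicate number as a block, leaving out each array, a fold rule without a test, and counting genes in place of probe sets. The test was tried on 20 simulated datasets of 22746 probe sets, each with 200 changed. At a log2 size of 1, 8.24% of the changed probe sets were called, against 88.7% at 2 and 97.4% at 3. Of all calls, 5.07% were false. A list of 3 genes moved by 1 was found in 20 of 20 datasets, and 2 of 260 unmoved lists were called. Every probe set was drawn independently, with variances from the fitted prior. The simulation thus held no correlation between genes and no shift of dim probe sets. Its error rates may not hold for these arrays.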

Results

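Transcript levels in expanded leaves of short-day plants were compared between Columbia, the reference accession, and jaw-D, a mutant that overexpresses miR319a, a microRNA that guides the cleavage of transcripts of several TCP transcription factors. Each genotype had 2 arrays. Median signals were 76.7 and 77.2 on the Columbia arrays and 74.6 and 76.5 on the jaw-D arrays. The share of probe sets with a signal under 16 was 17.8% and 18.4% in Columbia against 22.2% and 21.7% in jaw-D. Pearson correlations of log2 signals across probe sets, which are not independent replicates, were 0.983 between the Columbia arrays and 0.984 between the jaw-D arrays, and ran from 0.971 to 0.977 between genotypes. The ratio of 3' to 5' signal of the GAPDH control was 2.06 on jaw-D array 1 and 1.41, 1.43 and 1.36 on Columbia arrays 1 and 2 and jaw-D array 2. A second GAPDH design gave 1.16 on jaw-D array 1, within the range of 1.04 to 1.24 over the arrays, while jaw-D array 1 had the highest actin ratio in both actin designs, at 11.9 and 2.56 against at most 10.8 and 2.07 on the others. The 25S rRNA control read 3146 and 2760 on arrays 1 of Columbia and jaw-D, and 800.4 and 407.9 on their arrays 2.

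Of the 43 probe sets called between jaw-D and Columbia leaves, 35 fell, a share of 81.4% that was 59.6% of 287 calls when only probe sets at or above the median mean signal were tested. AT5G03350, a legume-lectin family gene that responds to salicylate, went from 4280 ± 847 in Columbia to 778 ± 27.4 in jaw-D (mean signal ± SD, n = 2 arrays each) and fell by 2.42 on the log2 scale. AT3G22240 dropped from 11939 ± 823 to 2187 ± 415. SWEET13, a sucrose transporter, and PDF1.2b, a jasmonate-responsive plant defensin, also fell, by 1.65 and by 1.48. Among the rises was EXLB1, an expansin-like cell-wall gene, which went from 70.8 ± 5.09 to 229 ± 7.71, a log2 difference of 1.50.

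With limma and Benjamini-Hochberg adjustment, 43 of 22746 probe sets passed the threshold, 8 higher and 35 lower in jaw-D, and all 43 differed at least 2-fold on the log2(signal + 16) scale. The smallest of these differences was 1.48 in size, and the range ran from -4.97 to 2.52. With so few arrays a much smaller difference could hardly pass the test. In the simulation, 8.24% of probe sets changed by 1 were called. The lack of smaller calls thus does not show that smaller differences are absent. At an unadjusted p under 0.05 there were 2957 probe sets, against 1137 by chance, 1031 higher and 1926 lower. After quantile normalization that split was 1333 higher and 1254 lower, while the calls were 7 higher and 29 lower. Of the 43, 21 represented 1 named gene each, 1 represented several genes and 21 were not named here. The largest falls of all were in probe sets not named here, with log2 differences of -4.97 and -4.23, and the largest rises among those not named were 2.36 and 2.27. Without any 1 of the 4 arrays, limma called 0 probe sets, with 2492 at an unadjusted p under 0.05 without Columbia array 1, 1978 without Columbia array 2, 2466 without jaw-D array 1 and 2235 without jaw-D array 2. The count was 287 over probe sets with a mean at or above the median, where fewer were tested and the prior degrees of freedom were 6.85, and 0 with a pseudocount of 1, where 2538 had an unadjusted p under 0.05.

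**Figure D1:**
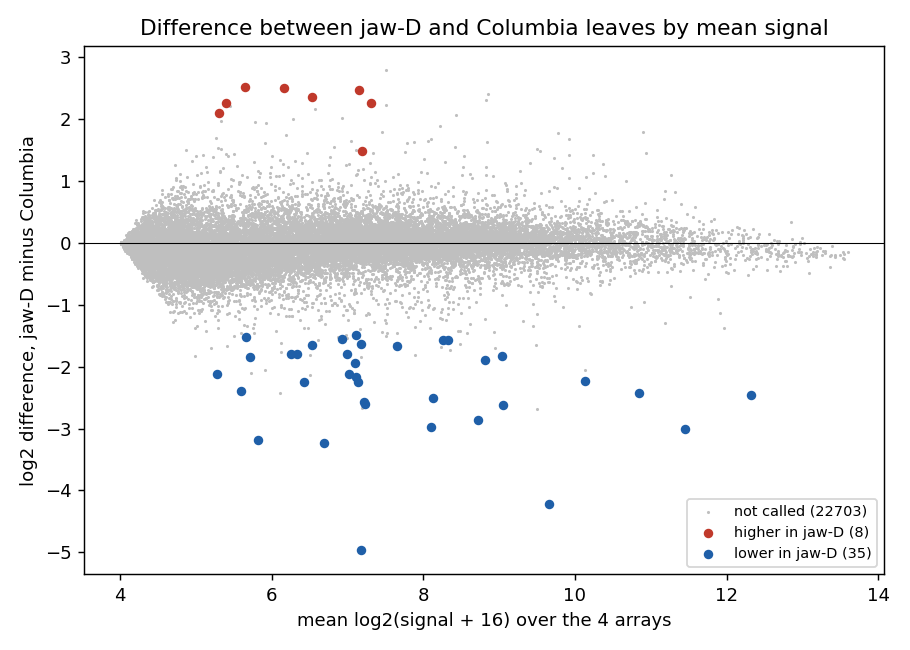
Log2 difference, jaw-D minus Columbia, of 22746 probe sets (vertical axis) against the mean log2(signal + 16) over the 4 arrays (horizontal axis). Red points mark the 8 called probe sets that were higher in jaw-D and blue points the 35 that were lower, which reach -4.97, and grey points were not called.

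Among named genes with a mean signal at or above the median of all probe sets, the 8 largest falls began with AT3G60420, which went from 307 ± 90.4 to 18.7 ± 11.2, a log2 difference of -3.23 ± 0.30 (SE) with an adjusted p of 0.0343 by limma. Its other probe set was dim, at 16.4 ± 8.13 in Columbia and 10.4 ± 2.76 in jaw-D, and was not called, with a log2 difference of -0.28 and an adjusted p of 0.662. AT2G32160, a methyltransferase family gene, fell by 2.62 (SE 0.18, adjusted p = 0.0212), and AT3G05730 fell by 2.60 (SE 0.19, adjusted p = 0.0215). AT3G22240 fell by 2.45 (SE 0.19, adjusted p = 0.0235), and AT5G03350 had an SE of 0.19 and an adjusted p of 0.0237. AT1G19960 fell by 2.23, AT1G13470 by 2.13 and AT2G29290, a gene of the tropinone reductase-like family, by 1.83, with adjusted p of 0.0444, 0.0420 and 0.0313. As the naming rule required, both jaw-D arrays lay below both Columbia arrays for each of these 8 genes.

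Both rises that met the naming rule were in genes with low signal in Columbia. AT1G65500 went from 44.4 ± 3.89 to 322 ± 58.8, a log2 difference of 2.47 (SE 0.18, adjusted p = 0.0215), and EXLB1 had an SE of 0.15 and an adjusted p of 0.0427. AT2G38870 had a log2 difference of 1.61 and an adjusted p of 0.0691 by limma, and AT3G16530 had 1.30 and 0.0759. Neither passed, and both were higher on both jaw-D arrays, which their selection required. All of these values came from probe sets of 1 gene.

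**Figure D2:**
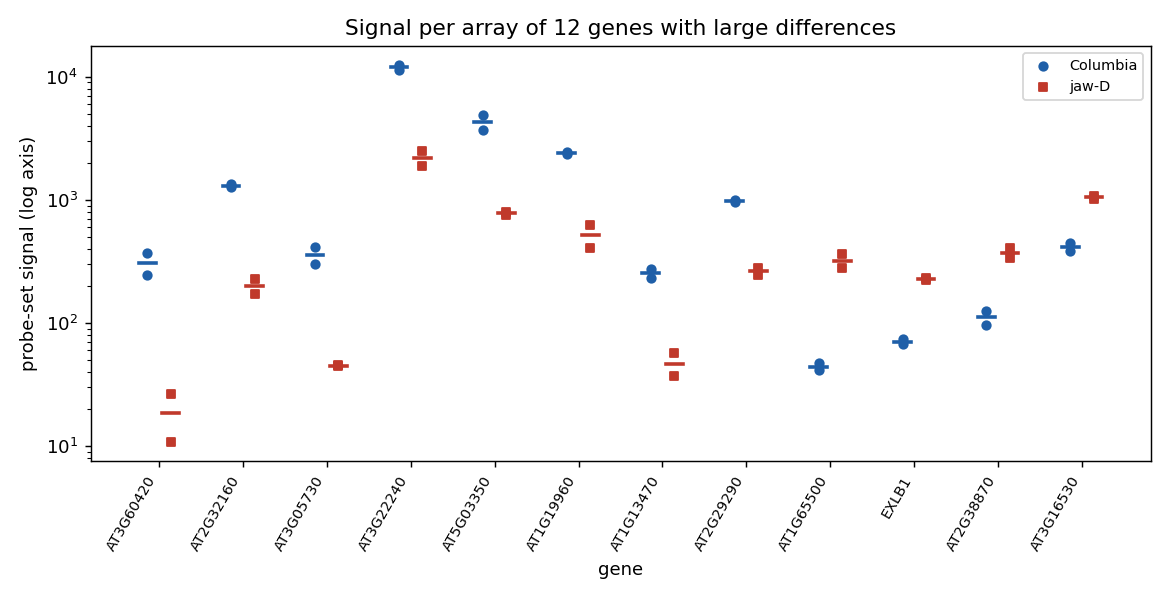
Probe-set signal on a log axis for 12 genes, with blue circles for the 2 Columbia arrays, red squares for the 2 jaw-D arrays and a bar at each mean. The 8 genes on the left fell, AT1G65500 and EXLB1 rose, and AT2G38870 and AT3G16530 did not pass the test.

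The other 11 called genes, chosen after their values were seen because they complete the set, comprised 10 falls and 1 rise. AT3G48080, a homologue of the immune regulator EDS1, fell by 1.79, and AT5G59670, a leucine-rich repeat receptor kinase gene, fell by 1.66. For AT1G31690, a copper amine oxidase gene, the dimmer of its probe sets fell by 2.12. The brighter one, at 174 ± 27.5 in Columbia and 28.2 ± 12.7 in jaw-D, had a log2 difference of -2.13 and was not called, with an adjusted p of 0.0603. The serine carboxypeptidase-like gene scpl46 fell by 1.57, the transcribed pseudogene AT3G48650 by 1.55, and log2 differences were -2.40 for AT5G62280, -2.24 for AT3G16670 and -1.52 for AT5G57760. AT2G15220, of a basic secretory protein family, rose from 14.4 ± 6.15 to 156 ± 20.9, with a log2 difference of 2.51. Its probe set and that of PDF1.2b are of designs that can also bind related transcripts. The size of the change depended on the pseudocount and the other settings for the dimmest of these. Over the settings run, AT1G31690 ranged from -4.18 to -0.95, AT5G62280 from -4.10 to -1.2, AT5G57760 from -2.25 to -0.78 and AT2G15220 from 1.49 to 3.41. With a pseudocount of 64 the differences of AT3G60420, AT3G16670, AT3G48080 and SWEET13 were -2.15, -1.43, -1.09 and -1.08.

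Auxin response genes were lower in jaw-D as a list. GH3.5 and GH3.3, which encode enzymes that conjugate auxin to amino acids, had log2 differences of -1.43 (SE 0.16) and -1.28 (SE 0.33), and IAA29, an Aux/IAA repressor gene, had -1.17 (SE 0.16). All 3 measured members of 13 were lower on both jaw-D arrays. None passed over all probe sets, with adjusted p of 0.0578, 0.242 and 0.0935, and 3 of 3 passed adjusted over the list alone. The list had a median log2 difference of -1.28. Camera gave it an adjusted p of 3.59e-04, which became an adjusted p of 0.438 with an estimated correlation. The median was -0.83 with a pseudocount of 64 and -1.88 with a pseudocount of 1. GH3.3 read 0.75 ± 0.21 in jaw-D, at the bottom of the range of signals, so its difference depends on the pseudocount, and it was -0.77 without Columbia array 1.

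Anthocyanin and flavonoid synthesis genes were higher in jaw-D as a list. UF3GT and UGT75C1, glycosyltransferase genes of anthocyanin synthesis, were 2.13-fold and 2.31-fold higher on the log2(signal + 16) scale, with SE of 0.19 and 0.36 on the log2 scale, and DFR, which encodes dihydroflavonol reductase, had a log2 difference of 0.53 (SE 0.19). Without Columbia array 1 DFR had 0.32, and without Columbia array 2 UGT75C1 had 0.75. Signals were low throughout, at 29.9 ± 8.70 against 80.9 ± 7.14 for UF3GT and 12.2 ± 12.2 against 47.6 ± 19.7 for UGT75C1. The 3 measured members of 12 did not pass over all probe sets, and 3 of 3 passed adjusted over the list alone. The list had a median log2 difference of 1.09. The camera test gave it an adjusted p of 0.00114, against an adjusted p of 0.438 with an estimated correlation. The median was 0.55 with a pseudocount of 64 and 1.43 with a pseudocount of 1.

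Both jasmonate lists were lower in jaw-D by the same test, each on 2 measured members. For biosynthesis, OPCL1, which encodes a ligase for jasmonate precursors, went from 683 ± 3.32 to 422 ± 8.91, a log2 difference of -0.67 (SE 0.14), and JMT, which encodes jasmonate methyltransferase, had -0.68 (SE 0.17). JMT was dim, at 35.4 ± 0.35 in Columbia and 16.3 ± 5.23 in jaw-D. Neither gene passed over all probe sets and 2 of 2 passed adjusted over the list alone. Camera gave this list an adjusted p of 0.0206, and an adjusted p of 0.483 with an estimated correlation. For the response, the defensin gene PDF1.2 went from 152 ± 8.84 to 41.2 ± 8.70, a log2 difference of -1.56 (SE 0.17) with an adjusted p of 0.0542 over all probe sets, and the thionin gene THI2.1 had -0.42 (SE 0.30), with a range of -0.77 to -0.06 when 1 array was left out. THI2.1 was also dim, at 27.6 ± 14.8 in Columbia and 16.4 ± 9.05 in jaw-D, and its replicates overlapped between genotypes. Of the 2 response genes, 0 passed over all probe sets and 1 passed adjusted over the list alone. The response list had a median of -0.99 and an adjusted p of 0.0352, and an adjusted p of 0.553 with an estimated correlation. This call was also lost with fry (adjusted p = 0.114), a pseudocount of 1 (0.086) and a floor on low signals (0.169), and the median was -0.61 with a pseudocount of 64. Calls on both jasmonate lists were lost without Columbia array 1, with medians of -0.67 and -0.79 and adjusted p of 0.085 and 0.225, and without jaw-D array 1, with medians of -0.60 and -0.77 and adjusted p of 0.0722 and 0.166.

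**Figure D3:**
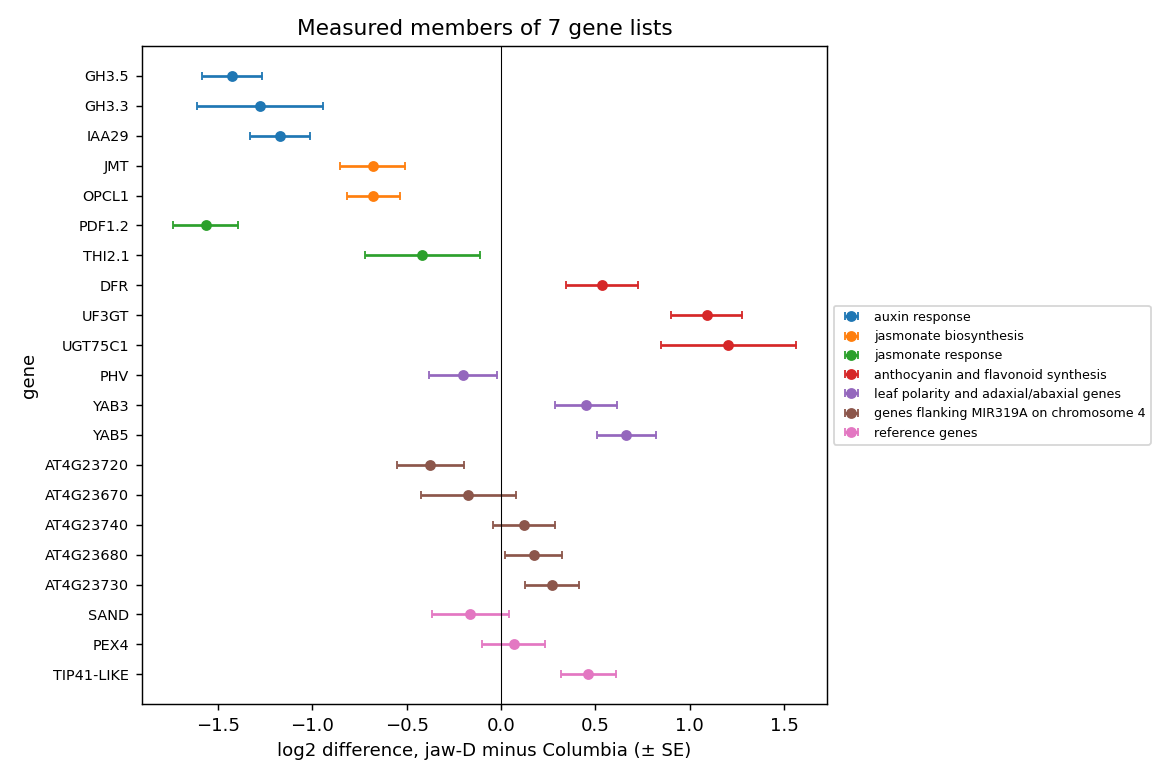
Log2 difference, jaw-D minus Columbia, with its SE for the measured members of 7 gene lists, 2 arrays per genotype. The 3 auxin and 4 jasmonate genes lie below 0, the 3 anthocyanin genes lie above it, and the genes beside MIR319A and the reference genes lie on both sides.

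Of the 9 genes beside MIR319A on chromosome 4, 5 were measured and none was called by limma, 0 over all probe sets and 0 adjusted over the list alone. AT4G23730 had a log2 difference of 0.27 (SE 0.14), AT4G23680 of 0.17, AT4G23740 of 0.12, AT4G23670 of -0.17 and AT4G23720 of -0.37 (SE 0.18). The smallest unadjusted p of the 5 was 0.0843, and camera gave the list an adjusted p of 0.687. TCP15, the 1 measured gene of 18 TCP genes without a miR319 site, went from 158 ± 24.3 to 330 ± 54.4, a log2 difference of 0.99 with an adjusted p of 0.157. With 1 member, its p adjusted over the list alone is its unadjusted p of 0.00227.

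Leaf polarity genes gave YAB5 a log2 difference of 0.66 (SE 0.16) and YAB3 one of 0.45, both abaxial regulators, against -0.20 for PHV, an adaxial one. No member passed over all probe sets, 1 passed adjusted over the list alone, and camera gave the list an adjusted p of 0.122. The cytokinin response regulators ARR16 and ARR15 had -0.91 and 0.34, with 0 called over all probe sets, 1 adjusted over the list alone, and an adjusted p of 0.732 for the list. For cold response, COR15A had -0.49 with an adjusted p of 0.348, and with 1 member its p adjusted over the list alone is its unadjusted p of 0.0370. The clock gene GI had -0.24 and the trichome regulator TRY had -0.37, and neither passed over all probe sets. Each was also the only measured member, with an unadjusted p of 0.146 and 0.111.

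In the remaining lists 0 members passed over all probe sets and 0 adjusted over the list alone. Leaf senescence had WRKY6 at 0.86, SAG101 at -0.32 and WRKY53 at -0.19, so that its median was -0.19 while its mean was 0.12 and camera's direction was up, with an adjusted p of 0.761. The Aurora kinase genes AUR1 and AUR2 had -0.25 and -0.18, with an adjusted p of 0.636 for the cell cycle list. LHCB4.1 and RCA, of photosynthesis, had -0.19 and -0.17, and an adjusted p of 0.636 for the list. LHCB4.1 turned to 0.01 with quantile normalization. The gibberellin receptor genes GID1B and GID1A had -0.18 and 0.08, with an adjusted p of 0.957. Root markers EXPA18, PYK10 and EXPA7 had -0.49, 0.17 and -0.04, with an adjusted p of 0.761, and EXPA7 turned to 0.12 with quantile normalization. The stomatal lineage genes SPCH, FAMA and MUTE had 0.47, 0.11 and -0.09, with an adjusted p of 0.517. Reference genes TIP41-LIKE, PEX4 and SAND had 0.46, 0.07 and -0.16, with an adjusted p of 0.517.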

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

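The settings here were fixed before the data were examined, but the check of pairing and the other splits of the arrays were not among them. All 21 called named genes kept their direction under every setting in which they were tested, which leaves out the filter on brighter probe sets for 6 of them. All 21 had replicates apart and differences of at least 1.48 in size, so these settings could hardly turn a direction. The 43 calls became 36 with quantile normalization (7 higher, 29 lower), 42 with median centring, 41 with robust moderation, 56 with a pseudocount of 64 and 42 when genes were counted. They became 287 over probe sets at or above the median mean signal (116 higher, 171 lower, 31 shared), 225 at or above the 25th percentile, 103 with an intensity trend and 344 by fold and replicates apart alone, where fewer probe sets tested, a larger prior or no test applies. They became 1 with a floor of 20.9, where 2697 had an unadjusted p under 0.05, 0 with a pseudocount of 1, and 0 without each array in turn, where 1 genotype has a lone array assumed to vary like the other. Counts of 2-fold differences were 166, 193, 96, 1, 0 and 0 for the 2 filters, the trend, the floor, the pseudocount of 1 and each array left out. Same-numbered arrays deviated with a correlation of -0.0743, which gave no sign of pairing, although the 25S rRNA control was higher on array 1 of both genotypes, and the labels do not say what a number shares. The replicate block gave 66 calls, 40 shared, and changed no list call. All 66 were 2-fold, which the size of difference needed to pass makes likely in advance. The other 2 splits of the 4 arrays gave 0 calls against 43, and 520 and 760 at an unadjusted p under 0.05 against 2957. Each of them puts 1 array of each genotype in both groups. A difference between genotypes then widens the spread within groups and makes calls unlikely, so these counts are no measure of chance. With 3 splits, none can reach a share under 0.05.

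Over the brighter probe sets 0 lists were called, but none of the 4 called lists kept the 2 members needed for a test there. Of the 4, 0 remained with an estimated correlation (medians 1.09, -1.28, -0.677 and -0.99, adjusted p 0.438, 0.438, 0.483 and 0.553 for anthocyanin, auxin, jasmonate biosynthesis and response), and 2 to 4 without 1 array. The estimated correlations were -0.291, -0.489, -0.963 and 0.851 for anthocyanin, auxin, jasmonate biosynthesis and response. With 2 residual degrees of freedom they are imprecise. They were negative for anthocyanin, auxin and jasmonate biosynthesis, so the calls lost there cannot come from members estimated to vary together. For jasmonate response the lost call does not show that members vary together. Jasmonate response lost its call with a floor (-0.902, adjusted p 0.169), a pseudocount of 1 (-1.30, 0.086) and fry (-0.99, 0.114). Without 1 array its median ran from -1.21 to -0.768 and that of jasmonate biosynthesis from -0.749 to -0.604. Robust moderation was not run for lists. Directions turned only in results that were not called, and the cause was not tested. With quantile normalization the root list turned to 0.125, EXPA7 to 0.125 and LHCB4.1 to 0.00516. The direction by camera turned for senescence with a floor (median -0.188) and gibberellin with a trend (-0.053). Without 1 array the ranges were -0.42 to 0.135 for senescence, -0.332 to 0.258 for root and EXPA7, -0.518 to -0.0599 for cytokinin, where camera turned, -0.508 to 0.163 for AT4G23670, -0.0164 to 0.257 for AT4G23740, -0.512 to 0.0177 for AUR1, -0.0798 to 0.233 for GID1A, -0.51 to 0.135 for WRKY53, -0.408 to 0.0836 for SAND and -0.0794 to 0.215 for PEX4.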

Other observations

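The genes of this part, and all of its tests except those of quantile normalization at an unadjusted p, of plain probe sets and of replicate differences over all neighbours, were chosen after the results were seen. HAT2, an auxin-induced homeodomain gene outside the auxin list, went from 262 ± 69.6 in Columbia to 60.9 ± 12.2 in jaw-D, a log2 difference of -1.84 (SE 0.23) with an adjusted p of 0.0795 by limma. HAT2 was picked among genes with replicates apart, so being lower on both jaw-D arrays is no added evidence. GH3.5, GH3.3 and IAA29 were also lower on both. Outside the list, the GH3 genes GH3.17, GH3.9 and GH3.1 had log2 differences of 0.34, 0.26 and -0.16, and none was called. Some of the largest differences that missed the threshold were increases with wide spread between replicates, which missing it at such a size implies. AT4G29020 read 591 and 1870 on the jaw-D arrays against 131 and 260 in Columbia, with a log2 difference of 2.41 and an adjusted p of 0.216. AT5G48490 read 785 and 1258 against 136 and 257, with 2.31 and an adjusted p of 0.110.

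A run of chitinase-type genes on chromosome 2 was uneven. AT2G43620, AT2G43590 and CHI (AT2G43570) had log2 differences of 1.96, 1.62 and 1.68, with adjusted p of 0.129, 0.0795 and 0.356, while AT2G43610, AT2G43600 and AT2G43580, which lie among them, had -0.35, -0.07 and -0.16. The value of CHI rests on Columbia array 1, since it read 58.2 and 300.4 on the Columbia arrays and 483 and 465 on the jaw-D arrays. Of 22 gene families with at least 10 measured members, none passed camera. The UGT family, without UGT75C1 as grouped here, had 27 of 47 members higher, a median of 0.17 and an adjusted p of 0.171. Genes of the chloroplast genome had 56 of 69 lower, a median of -0.13 and an adjusted p of 0.171.

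Falls outnumbered rises, 35 to 8 among called probe sets and 1926 to 1031 at an unadjusted p under 0.05. Among called probe sets, falls were 80.6% of calls after quantile normalization. Calls were at least 1.48 in size, while this step moved the median difference of all probe sets only from -0.0405 to -0.000629. The share thus had little room to change, so it is weak evidence on scaling. Dim signals stay open there: 27 of the 31 called probe sets at or above the median signal fell, or 87.1%, but when those brighter probe sets were tested on their own, 171 of 287 calls were falls, or 59.6%. At an unadjusted p the excess was bound to dim probe sets, since falls made up 48.8% at or above the median signal and 75.7% below it. Quantile normalization also removed it, leaving 48.5% falls, so scaling at low signals, including the larger share of jaw-D probe sets under 16, may account for that part. A difference between the genotypes stays open for both parts and was not tested apart from these.

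Neighbouring genes differed together slightly: across 5820 pairs of consecutive genes, which are not independent replicates, the log2 differences correlated with r = 0.0552, outside the range of -0.0262 to 0.0243 that covers 95% of shuffled orders (permutation p = 0.001, the smallest that 1000 shuffles can give). Plain probe sets gave 0.0525, above their shuffled range of -0.0239 to 0.0249. However, 5760 of the 5820 pairs were already plain, and probe sets paired with several genes were in none. This test could therefore not decide whether binding to several genes contributes. Variation shared by neighbours between replicates is argued against over all pairs, where the larger correlation of a replicate difference was 0.0184. It stays open among plain probe sets at or above the median signal, where the Columbia replicates gave 0.0515 against 0.0428 for the genotypes, both inside their shuffled ranges. Over these 1440 pairs, neighbouring genes were thus not shown to differ together (permutation p = 0.09). Whether the lower values of dim probe sets in jaw-D contribute over all pairs was not tested.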
